A study of Homo sapiens with 8 samples.

How the data were processed

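RNA was measured in 8 libraries, 3 of tumour self-seeded cells (TSC), 3 of primary tumour cells (PC) and 2 of circulating tumour cells (CTC), grouped by their titles. Total RNA was extracted with a column kit for small samples, checked for quality, depleted of ribosomal RNA and sequenced on an Illumina instrument, per the labels' protocols. The deposited table holds counts per gene, whole numbers that were not normalized; per the submitters' processing notes, the tools named are STAR 2.5.3a and featureCounts 1.5.3 and the genome build is hg38. The gene annotation, the strand setting, the treatment of reads with several positions and any step that removed reads of the host are not given in the sources used here. All rows name a gene and all 8 columns match a sample by title.

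The table has 39533 rows, of which 22986 have a count in some library. By symbol, 36248 rows matched the gene reference, 577 more matched an older symbol and 2708 matched nothing. Of 19369 protein-coding rows, 3958 were at 0 in all libraries. Coordinates are those of the RefSeq annotation of GRCh38, the same build as hg38, with 1-based positions. Library pairs were compared for repeated deposits by a chi-square of counts over genes, and 0 pairs agreed within sampling noise. Mitochondrial rows held 2.93% to 7.45% of the counts.

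Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalization, glmQLFit and glmQLFTest). All 8 libraries entered 1 fit with a group factor, so that CTC, with 2 libraries, shares the estimate of spread, and 14255 genes were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. The SE of a log2 fold change is its size divided by the square root of the F statistic. Every adjusted p of a gene is from this test unless another is named. CPM values were computed from the total over tested genes with TMM factors.

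Before the data were examined, 34 gene lists were fixed, 27 of programmes and 7 of cell types: cell cycle, histones, hypoxia, glycolysis, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, epithelial and mesenchymal identity, interferon response, antigen presentation, NF-κB and inflammatory cytokines, immediate early genes, heat shock, the unfolded protein and integrated stress response, p53 targets, apoptosis regulators, cholesterol biosynthesis, NRF2 targets, Wnt targets, cancer stem cell markers, extracellular matrix, integrins, self-seeding mediators, angiogenesis factors, lysosome and autophagy, nuclear noncoding RNA, colonic epithelium, hepatocytes, erythroid cells, platelets, leukocytes, endothelial cells and fibroblasts. The 30 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over these 30 lists, and again with an estimated correlation and with fry. Counts of members are given over all genes and adjusted over the list alone.

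The genes to name were also fixed in advance. Among called genes with an average log2 CPM of at least 3, replicates that do not overlap between the groups and a symbol that is not that of a clone, small RNA, antisense transcript or pseudogene, the 10 largest rises and the 10 largest falls are named. Up to 4 members of each described list with the smallest adjusted p and a set of focus genes complete the rule. Some genes that this rule gives, both called and not called, are left out of the text. Other genes were chosen after their values were seen, namely further called members of lists and TM4SF1.

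The scripts were tested on simulated counts drawn from the means and library sizes of these samples. Of genes changed 2-fold and 4-fold, 42.4% and 70% were recovered for TSC against PC (14014 genes), 12.1% and 68.4% for CTC against PC (13991 genes) and 24.2% and 75.3% for TSC against CTC (13976 genes). False calls were 6 of 118, 2 of 81 and 10 of 107.

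Alternatives fixed in advance were DESeq2 size factors, no filter on low counts, a stricter filter, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, only the libraries of the 2 groups, the replicate number as a block, removal of mitochondrial and small noncoding genes, each library left out in turn and a fold minimum of 1.5. The expression that defines small noncoding genes was corrected after its results had been seen. A correction for GC content and length of the longest transcript (known for 92.7% of tested genes) and thinning of all libraries to the shallowest were added after the data were seen. A change of sign was counted as a reversal where the value passed its threshold under either setting. For a list the direction is that of its test, which can differ from the sign of its median. This definition and the rule that picked the results with unequal TSC and CTC effects were chosen after results were seen. Where a group had 0 counts, a fold is a bound computed with 3 counts over the group, and with 1 to 3 counts it is a ratio of pooled counts with an exact 95% interval. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.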

Results

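Transcriptomes were measured in 8 libraries of HCT116 cells, a human colorectal cancer cell line, recovered from a model of tumour self-seeding, the return of circulating tumour cells to a tumour. The groups were tumour self-seeded cells (TSC, n = 3), primary tumour cells (PC, n = 3) and circulating tumour cells (CTC, n = 2). Per the labels, TSC and PC came from the primary tumour and CTC from blood. The series title names liver cancer whereas the labels name a colorectal line, and the host animal is not given in the sources used here. Total RNA was depleted of ribosomal RNA, so transcripts without a poly(A) tail, such as histone mRNAs, were counted as well.

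Total counts ranged from 4578869 to 14717833 in TSC and from 10864761 to 19264595 in PC, and were 957607 and 10524069 in the 2 CTC libraries. A count of 0 therefore allowed up to 3.13 CPM (counts scaled to a common library total) in CTC replicate 1 and up to 0.285 CPM in CTC replicate 2, with 3 counts as the floor. In the other libraries the floor lay between 0.156 and 0.655 CPM. These floors, and the intervals given for low counts, cover counting error alone. Of 39533 genes in the table, 16547 were at 0 in all 8 libraries, among them the housekeeping genes RPS25, NDUFS1 and UQCRC2, so a 0 in this table does not show that a gene was silent. Mitochondrial genes that encode proteins have 0 rows in the table. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

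PC libraries resembled each other most, with Spearman correlations across genes of log2 CPM between 0.981 and 0.988, against 0.96 to 0.981 among TSC libraries and 0.948 between the CTC libraries (genes are not independent replicates). The leading principal component held 36.8% of the variance and set the CTC libraries (scores of −107 and −52.7) apart from the others (−2.97 to 39.5). Component 2 (24.3%) parted the CTC libraries from each other, at −59.2 and 70.4, with TSC replicate 1 at 54.6. Component 3 (15.8%) parted TSC replicate 1, at 71.2, from CTC replicate 2, at −53.5. CTC replicate 2 correlated with CTC replicate 1 (0.948) less than with each TSC library (up to 0.959) or with PC replicates 1 and 2. CTC replicate 1, the shallowest library, correlated with CTC replicate 2 more than with any other library (next PC replicate 2, 0.9435). Its low depth may lower all its correlations. The CTC libraries also differed between themselves: FGFBP1 was at 2.99 and 92.1 CPM and CYP24A1 at 101 and 11.7 CPM in CTC replicates 1 and 2. MKI67, a proliferation marker, varied most widely in TSC, at 186, 1130 and 488 CPM in replicates 1 to 3, against 798 to 932 CPM in PC. Summed over the cell cycle list, TSC replicates 1 to 3 held 8365, 6677 and 8191 CPM, the reverse order, and PC 6752 to 7540 CPM. MKI67 alone therefore does not rank the TSC libraries by proliferation.

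The comparison of TSC with PC asks how self-seeded cells differ from the other cells of a primary tumour. The interferon-stimulated genes IFIT1 and IFI6 fell in TSC. IFIT1, which binds foreign RNA, was 5.78-fold lower than in PC (log2 fold change −2.53 ± 0.26 SE, n = 3 and 3, adjusted p = 0.000557 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and IFI6 was 5.54-fold lower (−2.47 ± 0.23, adjusted p = 0.00048). FGFBP1, a secreted carrier of fibroblast growth factors, was 18.7-fold higher in TSC (4.22 ± 0.59, adjusted p = 0.00395), TPPP3, a tubulin-binding protein gene, 12.8-fold higher (3.68 ± 0.50, adjusted p = 0.00373), and PLPP1, a lipid phosphatase gene, 7.67-fold higher (2.94 ± 0.36, adjusted p = 0.00164). FGFBP1 was not called without PC replicate 2 (adjusted p = 0.0549).

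In all, 72 of 14255 tested genes passed, 32 higher and 40 lower in TSC, and 62 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1469. FGFBP1 lies on chromosome 4 (15935577 to 15938740, hg38), TPPP3 on chromosome 16 (67389809 to 67393498), PLPP1 on chromosome 5 (55424854 to 55534964) and RCAN1, which encodes a calcineurin regulator, on chromosome 21 (34516442 to 34615113). RCAN1 rose from 16.7 ± 2.81 CPM (SD) in PC to 108 ± 23.2 CPM in TSC (log2 2.68 ± 0.32, adjusted p = 0.00164). Of the other genes with the largest rises, the connexin 43 gene GJA1 rose by 3.35 on the log2 scale, the siderophore-binding gene LCN2 by 2.88, the carboxypeptidase gene CPA4 by 2.59, the Golgi mannosidase gene MAN1A1 by 2.31, the glycosyltransferase gene GALNT5 by 2.09 and the transporter gene SLC16A6 by 2.08. Their adjusted p ran from 0.00164 for MAN1A1 to 0.0277 for LCN2, which was unevenly high in TSC (25.7 ± 23.3 CPM).

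Among the genes with the largest falls, CYP24A1, which encodes an enzyme that degrades vitamin D, went from 98.0 ± 22.5 CPM in PC to 11.1 ± 5.70 CPM in TSC (log2 −3.07 ± 0.55, adjusted p = 0.0205). BAMBI, a TGF-β pseudoreceptor gene, was at −1.88 ± 0.22 (adjusted p = 0.00164), the TGF-β-induced gene PMEPA1 at −2.32 ± 0.48 (adjusted p = 0.0477), the Notch target HES1 at −1.64 ± 0.34 (adjusted p = 0.0486) and the long noncoding RNA LNCAROD at −1.64 ± 0.23 (adjusted p = 0.00395). LAMP3, an interferon-inducible lysosomal gene, was at −1.78 ± 0.33 (adjusted p = 0.0255). MMP7, the gene of the protease matrilysin, was 13.4-fold lower (−3.75 ± 0.71, adjusted p = 0.0294), at 0.353 to 1.34 CPM in TSC and 6.54 to 9.72 CPM in PC.

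Of 27 tested interferon response genes, 10 fell in TSC, 0 rose and 17 were not called over all genes, and 19 fell when adjusted over the list alone. The fold change was negative for 26 of the 27, with a median of −1.16 and a mean of −1.51. The list was lower than other genes by camera (adjusted p = 3.11e-37), and this held with an estimated correlation (adjusted p = 0.0239). BST2, which tethers virions to the cell, was 5.18-fold lower (−2.37 ± 0.39, adjusted p = 0.0118), the antiviral sensor gene OAS1 3.66-fold lower (−1.87 ± 0.29, adjusted p = 0.00854). Antigen presentation genes were not called as a list (median −0.10, adjusted p = 0.536).

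**Figure D1:**
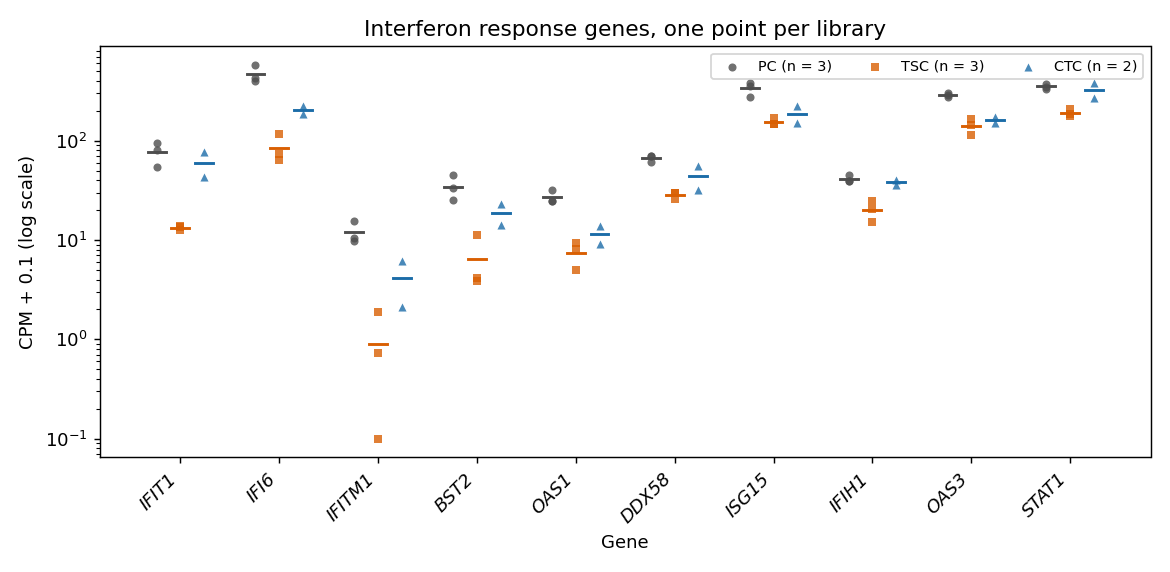
CPM plus 0.1 on a log axis for the 10 interferon response genes called lower in TSC than in PC, with 1 point per library and a bar at each group mean (PC n = 3, TSC n = 3, CTC n = 2). All 3 TSC libraries lie below all 3 PC libraries for each of the 10 genes, and IFI6 averaged 84.4 CPM in TSC, 470 CPM in PC and 204 CPM in CTC.

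Hypoxia response genes lay lower in TSC as a list, with 28 of 29 negative and a median of −0.68 (camera adjusted p = 1.11e-14, and adjusted p = 0.638 with an estimated correlation, where the call was lost). ANKRD37 was the member that fell over all genes (−1.50 ± 0.27, adjusted p = 0.0201), and 14 fell when adjusted over the list alone. PFKFB4 (−1.28 ± 0.30, adjusted p = 0.0998) and SLC2A1, the glucose transporter gene (−1.25 ± 0.31, adjusted p = 0.122), were not called. Immediate early genes lay lower too, with 25 of 28 negative and a median of −0.49 (camera adjusted p = 1.02e-09, and adjusted p = 0.708 with an estimated correlation). The median was −0.74 without TSC replicate 2. CCN1 (−1.62 ± 0.27, adjusted p = 0.0139) and FOSB (−1.19 ± 0.22, adjusted p = 0.0221) fell over all genes, and 12 members adjusted over the list alone. The list of Wnt targets and intestinal stem cell genes was called lower (median −0.30, adjusted p = 0.00573, and adjusted p = 0.767 with an estimated correlation). Of its 16 members the Wnt antagonist gene DKK1 fell (−1.14 ± 0.17, adjusted p = 0.00797), and 3 were lower and 1 higher when adjusted over the list alone. This list was not called without PC replicate 3 (adjusted p = 0.118) or by limma-voom (adjusted p = 0.0727), and its median was −0.49 without PC replicate 1.

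Another 5 lists lay slightly higher in TSC by camera. Cell cycle genes had a median of 0.24 (32 of 40 positive, adjusted p = 0.0045), histones 0.38 (22 of 25, adjusted p = 0.0045), heat shock proteins 0.33 (17 of 18, adjusted p = 0.0045), cholesterol biosynthesis 0.28 (21 of 25, adjusted p = 0.00291) and nuclear-encoded oxidative phosphorylation 0.11 (37 of 45, adjusted p = 0.0345). Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.767). All 5 were lost without 1 or more single libraries: cell cycle, cholesterol, heat shock and oxidative phosphorylation genes without TSC replicate 1 (adjusted p = 0.338, 0.337, 0.187 and 0.475), and histones without TSC replicate 3 (adjusted p = 0.783). Without PC replicate 1 the heat shock and cholesterol lists (adjusted p = 0.0534 and 0.0567), without PC replicate 3 the cell cycle, histone and oxidative phosphorylation lists (adjusted p = 0.0975, 0.202 and 0.703) and without TSC replicate 3 the cell cycle and oxidative phosphorylation lists (adjusted p = 0.14 and 0.294) were not called either. The median of oxidative phosphorylation was −0.003 without PC replicate 3. Where the lists stayed called, the medians of cell cycle, histones and oxidative phosphorylation were 0.38, 0.60 and 0.24 without TSC replicate 2, and that of oxidative phosphorylation 0.17 without PC replicate 2. Cell cycle was not called after all libraries were thinned to the shallowest (adjusted p = 0.0554), nor oxidative phosphorylation with a stricter filter (adjusted p = 0.0731). edgeR called 0 single members over all genes in these lists, and 1 cell cycle member and 0 of the others when adjusted over each list alone. Unadjusted p under 0.05 was reached by 8, 5, 3, 5 and 1 members in that order. DESeq2 called 1 cell cycle member and limma-voom 3 cell cycle and 3 histone members. The squalene epoxidase gene SQLE (0.58 ± 0.20, adjusted p = 0.345) and the chaperone gene HSPA8 (0.60 ± 0.23, adjusted p = 0.397) are examples.

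The remaining 21 lists with at least 5 tested members were not called in TSC against PC, with camera adjusted p from 0.0517 for extracellular matrix and proteases (median −0.10; MMP7 was the called member) to 0.95 for self-seeding mediators (median 0.07). Epithelial identity had a median of 0.06 (adjusted p = 0.585), mesenchymal identity of 0.21 (adjusted p = 0.15), cancer stem cell markers of 0.06 (adjusted p = 0.638; HES1 was the called member) and angiogenesis factors of 0.12 (adjusted p = 0.559), where the ephrin gene EFNB2 fell (−1.24 ± 0.20, adjusted p = 0.0123). The mesenchymal list was called higher without TSC replicate 1 (median 0.31, adjusted p = 0.0029), with no filter (adjusted p = 0.0346), by limma-voom (adjusted p = 0.0406) and after thinning (adjusted p = 0.0445). Its median was −0.02 without TSC replicate 3. Extracellular matrix was called lower without TSC replicates 2 or 3 or PC replicate 2 (adjusted p = 0.00485, 0.00819 and 0.008), with a stricter filter, with only the 2 groups and after thinning (adjusted p = 0.0257, 0.0305 and 0.0212). Integrins were called lower without PC replicate 1 (adjusted p = 0.01) and with no filter (adjusted p = 0.036). NF-κB and inflammatory cytokines were called higher without TSC replicate 1 (adjusted p = 0.0392) and NRF2 targets higher without TSC replicate 2 (adjusted p = 0.0189). Markers of leukocytes (median 0.51, or −0.27 without TSC replicate 3, adjusted p = 0.362), erythroid cells (0.12, adjusted p = 0.609), fibroblasts and stellate cells (−0.10, adjusted p = 0.609) and colonic epithelium (0.03, adjusted p = 0.824) were not called either. Median, mean and test differed in sign for glycolysis, apoptosis regulators, cancer stem cell markers, angiogenesis factors, erythroid cells and fibroblasts.

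The number of calls depended on single libraries. Leaving out 1 library at a time gave 153 calls without TSC replicate 2 (48 higher and 105 lower), 16 without TSC replicate 3 (12 higher and 4 lower), 25, 10 and 30 without PC replicates 1, 2 and 3, and 142 and 134 without CTC replicates 1 and 2. Of the 20 genes with the largest changes, 7 passed in all 8 of these fits: TPPP3, PLPP1, RCAN1, MAN1A1, IFIT1, IFI6 and BAMBI. HES1 passed in 2 of the 8, and LCN2 and PMEPA1 in 3. Other tools gave 191 (DESeq2) and 553 (limma-voom) calls. With no filter 114 were higher and 241 lower. A fold minimum of 1.5 left 13 higher and 6 lower, and leaving out PC replicate 2 left 6 and 4. Which direction held more calls thus depended on the setting.

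The comparison of CTC with PC asks how tumour cells in the blood differ from those in the primary tumour. Genes of blood cells were far higher in CTC. HBB, which encodes β-globin, was at 164 and 209 CPM in the CTC libraries and at 0 to 0.754 CPM in PC (log2 fold change 9.26 ± 0.53 SE, n = 2 and 3, adjusted p = 4.67e-07), and LYZ, the lysozyme gene of myeloid cells, rose 74.3-fold (6.22 ± 0.64, adjusted p = 0.000112). The immediate early genes EGR1 and FOSB fell, EGR1 7.15-fold (−2.84 ± 0.54, adjusted p = 0.0126) and FOSB 6.08-fold (−2.61 ± 0.28, adjusted p = 0.000134). The epithelial marker EPCAM was at 557 ± 15.1 CPM in CTC and 438 ± 41.0 CPM in PC and was not called (0.35 ± 0.17, adjusted p = 0.239).

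In all, 559 genes passed, 200 higher and 359 lower in CTC, and 470 of them changed at least 2-fold. Without CTC replicate 2 the split was 32 higher and 3 lower, without CTC replicate 1 240 and 576, with no filter 381 and 1154, and with a fold minimum of 1.5 it was 77 and 64. Unadjusted p under 0.05 was reached by 3362 genes. HBB lies on chromosome 11 (5225464 to 5227071, hg38), LYZ on chromosome 12 (69348381 to 69354234), VIM on chromosome 10 (17228241 to 17237593) and EGR1 on chromosome 5 (138465479 to 138469303). The 10 largest rises among the eligible genes included DOCK2, a guanine exchange factor gene of haematopoietic cells (8.31 ± 0.79, adjusted p = 6.73e-05), the lipoprotein gene APOE (6.51 ± 0.51, adjusted p = 9.14e-06), and CYBB, which encodes a subunit of the phagocyte NADPH oxidase (6.03 ± 0.63, adjusted p = 0.000121). TPPP3 rose by 4.82 on the log2 scale (adjusted p = 0.000192).

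Leukocyte markers rose as a list in CTC. The list has 27 genes in the table, of which 8 were at 0 in all libraries and 9 were tested. A gene nearly silent in PC and TSC passes the count filter only through CTC. The direction and median of the tested members are thus partly set by that filter. Of 9 tested members 6 were higher over all genes and 7 when adjusted over the list alone, and all 9 were positive with a median of 6.22 (camera adjusted p = 4.9e-18, and adjusted p = 0.0431 with an estimated correlation). ITGAM, a myeloid integrin gene, was 92.0-fold higher (6.52 ± 0.67, adjusted p = 0.000112), the leukocyte plastin gene LCP1 181-fold (7.50 ± 0.83, adjusted p = 0.000192) and CSF1R, the receptor gene of macrophage colony-stimulating factor, 36.9-fold (5.21 ± 0.59, adjusted p = 0.000269). PTPRC, the gene of the leukocyte antigen CD45, was at 31.9 and 7.63 CPM in CTC and at 0 to 0.503 CPM in PC (adjusted p = 0.0146). Summed over the list, CTC replicates 1 and 2 held 375 and 142 CPM, PC 21.8 to 28.9 CPM and TSC 36.5 to 53.9 CPM.

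Erythroid genes rose as well, with 3 of 7 tested members higher over all genes and 5 when adjusted over the list alone (median 7.14, or 4.75 with members at 0 in PC set to their bound, camera adjusted p = 7.61e-17, and adjusted p = 0.0431 with an estimated correlation). The same limit of the count filter applies to this list, with 7 tested of 18 genes in the table. ALAS2, the erythroid enzyme of haem synthesis, was 142-fold higher (7.14 ± 0.78, adjusted p = 0.000458). SLC4A1, the gene of the red cell anion exchanger, had 0 counts in PC and was at least 70.8-fold higher (adjusted p = 0.0138), with the floor of 3 counts taken over the group. The median fell to 0.35 without CTC replicate 2, where the list was still called (adjusted p = 2.75e-07). HBA2 was at 0 in all 8 libraries and the near-identical HBA1 at 0 in CTC. Of the 45 erythroid and leukocyte markers in the table, 21 were at 0 in both CTC libraries, and 16 of these at 0 in every library.

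**Figure D2:**
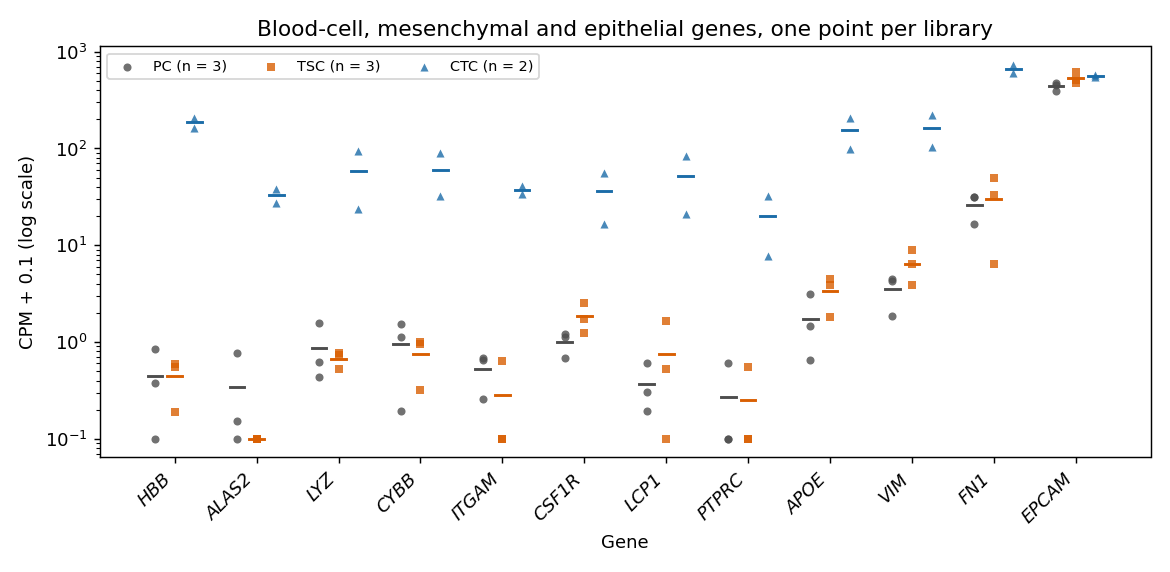
CPM plus 0.1 on a log axis for genes of erythroid cells, leukocytes and macrophages, the mesenchymal genes VIM and FN1 and the epithelial gene EPCAM, with 1 point per library and a bar at each group mean (PC n = 3, TSC n = 3, CTC n = 2). Both CTC libraries lie above all PC and TSC libraries for the genes from HBB to FN1, HBB at 164 and 209 CPM, whereas EPCAM lies between 438 and 557 CPM on average in the 3 groups.

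Mesenchymal identity genes were called as a list in CTC, with members in both directions. Of 16 tested members 4 were higher and 1 lower in CTC over all genes, and 6 and 2 when adjusted over the list alone (median 0.59, 9 positive, camera adjusted p = 0.000268, and adjusted p = 0.392 with an estimated correlation). The median was 0.05 without CTC replicate 1, 0.12 without CTC replicate 2 and −0.16 with no filter, while the test still called the list higher (adjusted p = 0.00752, 2.13e-05 and 0.00157). The 4 that rose were the intermediate filament gene VIM (45.5-fold, 5.51 ± 0.41, adjusted p = 8.15e-06), the fibronectin gene FN1 (25.4-fold, 4.67 ± 0.51, adjusted p = 0.000192), the transcription factor gene ZEB2 (108-fold, 6.75 ± 0.85, adjusted p = 0.000674) and TGFBI. All 4 are also expressed by macrophages. TGFBI had 1 count in PC, and the ratio of pooled counts was 344 with a 95% counting interval from 60.3 to 13700 (adjusted p = 0.00309). SPARC, a matrix glycoprotein gene, had 0 counts in CTC and was at least 23.7-fold lower (adjusted p = 0.0138). Epithelial identity genes lay lower in CTC, with 24 of 28 negative, a median of −0.45 and 2 members lower over all genes and 8 adjusted over the list alone (camera adjusted p = 0.000308, and adjusted p = 0.392 with an estimated correlation). These 2 were CDH3, the P-cadherin gene (−1.05 ± 0.23, adjusted p = 0.0225), and the protease inhibitor gene SPINT1 (−0.99 ± 0.26, adjusted p = 0.0458). The epithelial list was not called without CTC replicate 1 (adjusted p = 0.0573), and its median was −0.71 without CTC replicate 2.

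Immediate early genes fell in CTC, 11 of 28 over all genes and 17 adjusted over the list alone, with 0 higher (median −1.06, camera adjusted p = 3.62e-13, and adjusted p = 0.392 with an estimated correlation). EGR3 (−2.92 ± 0.51, adjusted p = 0.00811) and JUNB (−1.51 ± 0.25, adjusted p = 0.00653) were among them, and FOS was close to the threshold (−2.05 ± 0.54, adjusted p = 0.049). Hypoxia response genes fell in 5 of 29 cases over all genes and 18 adjusted over the list alone (median −0.90, or −0.57 without CTC replicate 2, camera adjusted p = 1.11e-09, and adjusted p = 0.392 with an estimated correlation). PFKFB4 was 4.64-fold lower (−2.21 ± 0.41, adjusted p = 0.0114) and SLC2A1 3.02-fold lower (−1.59 ± 0.36, adjusted p = 0.0277). Glycolysis genes were lower in 3 of 16 cases, and 8 adjusted over the list alone (median −0.49, camera adjusted p = 9.29e-05, and adjusted p = 0.392 with an estimated correlation), with the aldolase gene ALDOC at −1.24 ± 0.23 (adjusted p = 0.0108) and the phosphofructokinase gene PFKL at −1.04 ± 0.22 (adjusted p = 0.0198).

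Interferon response genes lay lower in CTC too, with 4 of 27 lower over all genes and 7 adjusted over the list alone (median −0.54, camera adjusted p = 0.000523, and adjusted p = 0.392 with an estimated correlation). IFI6 was 2.29-fold lower (−1.19 ± 0.26, adjusted p = 0.0231), OAS3 1.76-fold lower (−0.82 ± 0.20, adjusted p = 0.036) and ISG15 1.78-fold lower (−0.84 ± 0.21, adjusted p = 0.0425), and IFIT1 was not called (−0.43 ± 0.28, adjusted p = 0.376). Extracellular matrix and protease genes were lower in 7 of 30 cases and higher for FN1, with 13 lower and 1 higher adjusted over the list alone (median −1.22, camera adjusted p = 0.000523, and adjusted p = 0.459 with an estimated correlation). PLAU, the urokinase gene, was 3.79-fold lower (−1.92 ± 0.30, adjusted p = 0.00404) and the collagen gene COL17A1 4.66-fold lower (−2.22 ± 0.48, adjusted p = 0.022). Integrin and focal adhesion genes were lower in 4 of 27 cases and 8 adjusted over the list alone, with 0 and 1 higher (median −0.27, camera adjusted p = 0.0341, and adjusted p = 0.608 with an estimated correlation), among them the integrin gene ITGB4 (−1.44 ± 0.34, adjusted p = 0.0301). The integrin list was not called without PC replicate 3 or CTC replicates 1 or 2 (adjusted p = 0.229, 0.0814 and 0.0524). Wnt targets and intestinal stem cell genes were lower in 3 of 16 cases and 4 adjusted over the list alone (median −0.78, camera adjusted p = 0.00139, and adjusted p = 0.419 with an estimated correlation). RNF43, a Wnt receptor ubiquitin ligase gene, was 6.28-fold lower (−2.65 ± 0.42, adjusted p = 0.00437).

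Nuclear noncoding RNAs fell in 4 of 18 cases over all genes (SCARNA2, TERC, RMRP and RPPH1) and 6 adjusted over the list alone, with 0 and 2 higher (median −0.64, camera adjusted p = 0.00902, and adjusted p = 0.575 with an estimated correlation). TERC, the RNA of telomerase, was at −1.22 ± 0.23 (adjusted p = 0.0135). This list was not called without PC replicate 1 (adjusted p = 0.0692), and its median was −0.34 without CTC replicate 2. With small noncoding genes removed, members of the list among them, the median was −0.25, the list was not called (adjusted p = 0.963) and its test turned. Histone genes, whose near-identical copies share reads, were lower in 2 of 25 cases (H4C3 and H2BC11) and higher for H4C9, with 7 lower and 1 higher adjusted over the list alone (median −0.68, camera adjusted p = 0.000523, and adjusted p = 0.656 with an estimated correlation). The histone list was not called without CTC replicate 2 (adjusted p = 0.139). Cell cycle genes lay higher (median 0.23, 28 of 40 positive, camera adjusted p = 0.0111, and adjusted p = 0.696 with an estimated correlation), where ASPM rose (0.79 ± 0.20, adjusted p = 0.04) and 3 rose adjusted over the list alone. Heat shock (median 0.34, adjusted p = 0.0248, and adjusted p = 0.656 with an estimated correlation) and oxidative phosphorylation genes (median 0.21, adjusted p = 0.0341, and adjusted p = 0.756 with an estimated correlation) lay higher with 0 single calls by edgeR over all genes or adjusted over the list alone. Unadjusted p under 0.05 was reached by 5 and 2 of their members, DESeq2 called 0 and limma-voom 1 in each. Without CTC replicate 2 the cell cycle, heat shock and oxidative phosphorylation lists were not called (adjusted p = 0.225, 0.935 and 0.744), nor were cell cycle and oxidative phosphorylation without PC replicate 3 (adjusted p = 0.0554 and 0.301) and heat shock without PC replicate 1 (adjusted p = 0.0799) or with a stricter filter (adjusted p = 0.0773).

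The remaining 14 lists were not called, with camera adjusted p from 0.0786 for cancer stem cell markers (3 of 15 lower: CD24, SOX9 and HES1) to 0.906 for self-seeding mediators (SPARC lower over all genes, and 2 higher and 3 lower adjusted over the list alone). The stem cell list was called lower without TSC replicate 2, PC replicate 1 or CTC replicates 1 or 2 (adjusted p = 0.0438, 0.031, 0.0445 and 0.0471), with a stricter filter (adjusted p = 0.0119) and after thinning (adjusted p = 0.00166). Cholesterol biosynthesis was called lower without CTC replicate 2 (adjusted p = 0.0183). Single genes of these lists passed: NFKBIA, the NF-κB inhibitor gene, was 2.29-fold higher (1.19 ± 0.18, adjusted p = 0.00404), the matricellular gene THBS1 4.09-fold higher (2.03 ± 0.30, adjusted p = 0.00276), the thioredoxin reductase gene TXNRD1 1.95-fold higher (0.97 ± 0.23, adjusted p = 0.0331) and the p53 target GDF15 2.71-fold lower (−1.44 ± 0.29, adjusted p = 0.0171). PTGS2 had 0 counts in CTC and was at least 6.74-fold lower (adjusted p = 0.0438). Cytosolic ribosomal proteins (median −0.02, adjusted p = 0.872), fibroblast and stellate cell markers (median −0.61, adjusted p = 0.872) and colonic epithelium (median −0.55, adjusted p = 0.612) were not called. Neither were antigen presentation (−0.07, adjusted p = 0.872), NF-κB and inflammatory cytokines (0.19, adjusted p = 0.277), the unfolded protein and integrated stress response (0.08, adjusted p = 0.484), p53 targets (−0.15, adjusted p = 0.222), apoptosis regulators (0.02, adjusted p = 0.872), cholesterol biosynthesis (−0.14, adjusted p = 0.186), NRF2 targets (0.14, adjusted p = 0.253), angiogenesis factors (−0.30, adjusted p = 0.872) and lysosome and autophagy (0.16, adjusted p = 0.298). Lists for hepatocytes, platelets, endothelial cells and mitochondrially encoded transcripts had fewer than 5 tested members. Their median log2 fold change was −1.23, 0.31, 0.60 and −0.12 in CTC and −0.38, −0.53, 0.06 and 0.49 in TSC against PC. Median, mean and test differed in sign for ribosomal proteins, antigen presentation, NF-κB and inflammatory cytokines, apoptosis regulators and NRF2 targets.

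Genes lower in CTC were rich in G and C. Their transcripts had a median GC content of 57.6%, against 42.9% for the genes higher in CTC and 48.4% for all tested genes. In CTC replicate 1 the median deviation of log2 CPM from the gene mean was −0.43 in the class of genes with the highest GC content and 0.25 in the class with the lowest. With GC content and length corrected for, an alternative chosen after the data were seen, 237 of the 359 lower genes and 157 of the 200 higher genes were called again. Under this correction the integrin (adjusted p = 0.456) and oxidative phosphorylation lists (adjusted p = 0.224) were no longer called in CTC, nor were histones (adjusted p = 0.0633) and oxidative phosphorylation (adjusted p = 0.432) in TSC against PC, or extracellular matrix in TSC against CTC (adjusted p = 0.13). Ribosomal proteins in TSC against PC (adjusted p = 0.0164), and NF-κB and inflammatory cytokines (adjusted p = 0.0396) and stem cell markers (adjusted p = 0.0382) in CTC against PC, gained a call. Thinning to the shallowest library was chosen after the data were seen as well.

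**Figure D3:**
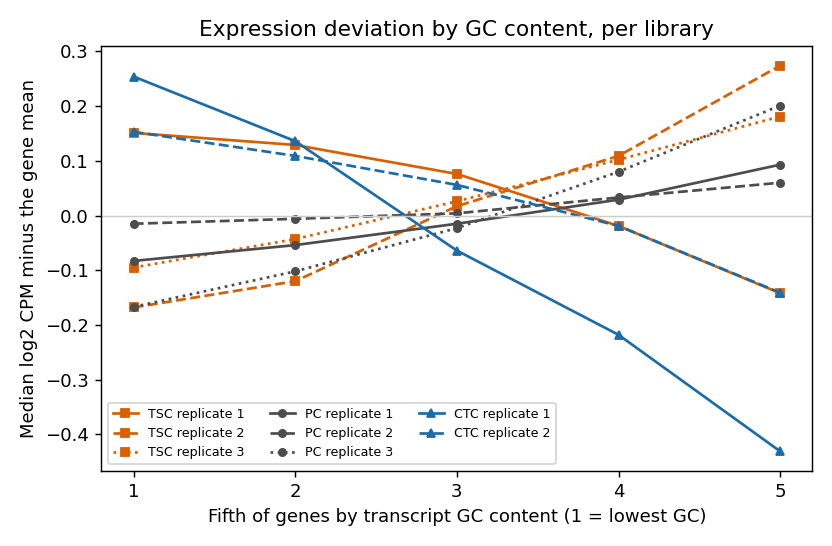
Median deviation of log2 CPM from the mean of each gene over the libraries (vertical axis) in 5 equal classes of genes ordered by transcript GC content (horizontal axis, 1 is the lowest), with 1 line per library. CTC replicate 1 runs from 0.25 in class 1 to −0.43 in class 5, the widest range of the 8 libraries. CTC replicate 2 and TSC replicate 1 also fall from class 1 to class 5, and the other libraries rise.

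The 10 largest falls among eligible genes were those of CEMIP (−3.95 ± 0.88), IGSF9 (−3.65 ± 0.46), RPS6KA2, ADAMTS7, RUNX2, RBPMS, BTBD11, EGR3, EGR1 and GRHL3 (−2.75 ± 0.63), with adjusted p from 7e-04 for IGSF9 to 0.0472 for RPS6KA2. Of the 20 genes with the largest changes, 10 passed in all 8 fits with 1 library left out, among them HBB, DOCK2, ZEB2, APOE, LYZ, CYBB, VIM, FN1 and EGR1. The other 10 lost their call without CTC replicate 2, with adjusted p from 0.075 for TPPP3 to 0.486 for ADAMTS7. Without CTC replicate 2, 35 genes were called. Other leave-one-out counts were 1575, 1054 and 285 without TSC replicates 1, 2 and 3, and 177, 182 and 154 without PC replicates 1, 2 and 3.

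TSC and CTC shared differences from PC. Higher in both were 19 genes and lower in both 13, and 0 were called in opposite directions by edgeR. DESeq2 gave 0 and limma-voom 1 such gene, and at an unadjusted p under 0.05 in both comparisons there were 18, beside 662 in the same direction. FGFBP1 was 14.2-fold higher in CTC (3.83 ± 0.61, adjusted p = 0.00523) as well as 18.7-fold in TSC, PLPP1 7.38-fold (2.88 ± 0.39, adjusted p = 0.00123), RCAN1 4.69-fold (2.23 ± 0.35, adjusted p = 0.00411) and CPA4 6.70-fold (2.74 ± 0.39, adjusted p = 0.00232). BAMBI (−1.43 ± 0.27, adjusted p = 0.0124), HES1 (−1.80 ± 0.44, adjusted p = 0.0366), CCN1 and LAMP3 were lower in both. The membrane protein gene TM4SF1, named here after its values were seen, had 1 count in PC. The ratio of pooled counts was 276 in TSC (95% counting interval 49 to 11000) and 447 in CTC (78.7 to 17800). FGFBP1, at 2.99 CPM in CTC replicate 1, was at about the floor of 3 counts (3.13 CPM), so its direction in that library is not resolved. The calls shared by TSC and CTC depended on CTC replicate 2. Without it the fold change of FGFBP1 turned to −0.39 (adjusted p = 0.864) and 2 genes were shared in place of 32.

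Independent lists of these sizes would share 0.45 higher and 1.01 lower genes. Because both comparisons use the same PC libraries, groups without any change were simulated against PC. Over 20 simulations the mean correlation of fold changes across genes was 0.352 (highest 0.37) and the mean covariance 0.109 (highest 0.122). At most 1 gene was shared. The simulations called on average 0.45 genes in TSC and 0.25 in CTC against PC, so hardly any could be shared. That shared count is therefore no measure for an overlap of lists of 72 and 559 genes. The data gave an observed correlation of 0.381 and covariance of 0.356. No split of 3 PC libraries leaves 2 in each part, and the controls were not split. Part of the overlap and of the covariance may therefore come from the shared controls. The overlap was 85, 11, 9, 4, 10, 81 and 2 genes without TSC replicates 2 and 3, PC replicates 1, 2 and 3, and CTC replicates 1 and 2, respectively.

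**Figure D4:**
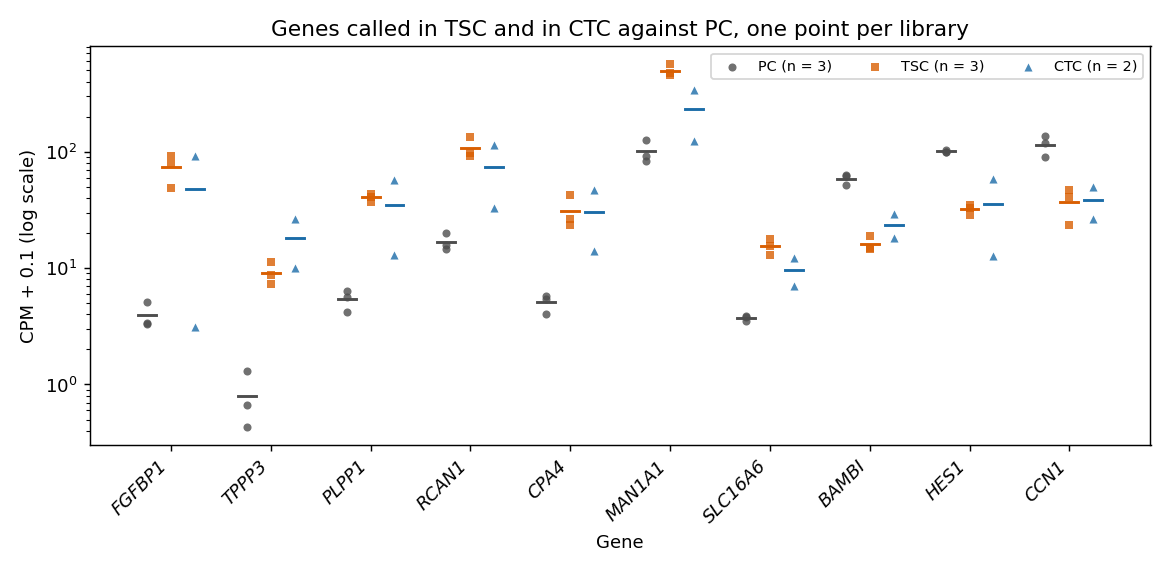
CPM plus 0.1 on a log axis for 10 genes called in the same direction in TSC and in CTC against PC, with 1 point per library and a bar at each group mean (PC n = 3, TSC n = 3, CTC n = 2). FGFBP1 is at 92.1 CPM in CTC replicate 2 and at 2.99 CPM in CTC replicate 1. The latter is at about the floor of 3 counts (3.13 CPM), so it is not resolved from the PC mean of 3.82 CPM.

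The contrast of TSC with CTC asks how cells that seeded a tumour differ from cells still in the blood, and it is also the test of whether the TSC and CTC differences from PC are equal. The genes of blood cells separated the groups most: HBB was lower in TSC (log2 fold change −9.08 ± 0.54 SE, n = 3 and 2, adjusted p = 8.99e-07), as were DOCK2 (−6.90 ± 0.74, adjusted p = 0.000199), LYZ (100-fold, −6.64 ± 0.68, adjusted p = 0.000143) and CYBB (−6.26 ± 0.66, adjusted p = 0.000179). IFIT1 was 4.29-fold lower in TSC than in CTC (−2.10 ± 0.29, adjusted p = 0.00186). IGSF9, an immunoglobulin superfamily gene, was 8.37-fold higher in TSC (3.06 ± 0.46, adjusted p = 0.00441) and the transcription factor gene RUNX2 7.36-fold higher (2.88 ± 0.60, adjusted p = 0.0382).

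Here 128 genes passed, 53 higher and 75 lower in TSC, 125 of them by at least 2-fold, and 2379 genes had an unadjusted p under 0.05. Which direction held more calls depended on the setting. There were 514 higher and 214 lower with no filter, 497 and 199 without TSC replicate 1, 117 and 51 without CTC replicate 1, 205 and 185 with DESeq2 and 230 and 210 with limma-voom. Without TSC replicate 2 the split was 47 and 48, without TSC replicate 3 it was 3 and 33, and without CTC replicate 2 it was 7 and 41. With only the 2 groups it was 10 and 72, and with a fold minimum of 1.5 it was 3 and 44. Of the 128, 115 were also called in TSC or in CTC against PC, a tally chosen after the data were seen. The other large falls included those of the cholesterol exporter gene ABCA1 (−6.20 ± 0.60), ZEB2, APOE, VIM (−4.59 ± 0.40) and FN1 (−4.45 ± 0.51), and the other large rises those of the prominin gene PROM2 (2.16 ± 0.41), the septin gene SEPTIN3, the calcium channel genes ORAI2 and CACNA2D2, KIRREL1, ZNF628, PHETA1 and the transcription factor gene NFIB (1.73 ± 0.36, adjusted p = 0.037). LNCAROD was 2.94-fold lower in TSC (−1.56 ± 0.26, adjusted p = 0.0104).

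Leukocyte markers were lower in TSC than in CTC, 5 of 9 over all genes, and 7 lower and 1 higher adjusted over the list alone (median −5.99, camera adjusted p = 1.25e-19, and adjusted p = 0.0289 with an estimated correlation). Erythroid genes were lower in 2 of 7 cases and 5 adjusted over the list alone (median −6.62, or −4.25 with bounds, camera adjusted p = 5.32e-18, and adjusted p = 0.0413 with an estimated correlation). ALAS2 had 0 counts in TSC and was at least 369-fold lower (adjusted p = 0.000328). As in CTC against PC, the tested members of both lists are partly those that passed the count filter through CTC. Without CTC replicate 2 the erythroid median was −0.23 and the list was still called (adjusted p = 1e-05). Mesenchymal genes were lower in 4 of 16 cases, the same 4 that rose in CTC, and 5 lower and 4 higher adjusted over the list alone (median −0.17, camera adjusted p = 0.00125, and adjusted p = 0.373 with an estimated correlation). The sign of that median was not stable. It was −0.075 without TSC replicate 1, 0.16 and 0.10 without CTC replicates 1 and 2, 0.11 with a stricter filter, 0.13 without small noncoding genes and 0.43 with no filter, while the test still called the list lower (adjusted p = 0.00482, 0.036, 0.00111, 0.017, 0.00476 and 0.0462). With limma-voom the median was 0.20 and the list was not called (adjusted p = 0.0515). Interferon response genes were lower in TSC in 2 of 27 cases, IFIT1 and IFI6, and 9 adjusted over the list alone (median −0.62, camera adjusted p = 4.89e-07, and adjusted p = 0.303 with an estimated correlation).

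Histone genes lay higher in TSC than in CTC, with 2 of 25 members higher over all genes, and 20 higher and 1 lower adjusted over the list alone (median 1.02, camera adjusted p = 2.69e-10, and adjusted p = 0.541 with an estimated correlation). H4C3 was 2.98-fold higher (1.58 ± 0.25, adjusted p = 0.0075). Immediate early genes lay higher, with FOSB called (2.66-fold, 1.41 ± 0.26, adjusted p = 0.0225) and 4 adjusted over the list alone (median 0.54, camera adjusted p = 8.91e-05, and adjusted p = 0.608 with an estimated correlation). The immediate early list was not called without CTC replicate 2 (adjusted p = 0.132), and its median was 0.32 without TSC replicate 2. Cholesterol biosynthesis genes lay higher (median 0.46, or 0.28 without TSC replicate 1, camera adjusted p = 5.01e-05, and adjusted p = 0.541 with an estimated correlation), where MVD was called (1.26 ± 0.27, adjusted p = 0.0406) and 6 adjusted over the list alone. Nuclear noncoding RNAs were higher in 3 of 18 cases, and 6 adjusted over the list alone (median 0.55, camera adjusted p = 0.00881, and adjusted p = 0.667 with an estimated correlation), and were not called as a list without TSC replicate 2 or CTC replicate 2 (adjusted p = 0.0858 and 0.121) or with small noncoding genes removed (adjusted p = 0.962), where the test turned. Extracellular matrix genes lay higher (median 0.94, camera adjusted p = 0.0245, and adjusted p = 0.667 with an estimated correlation), with PLAU higher (1.49 ± 0.30, adjusted p = 0.0322), FN1 lower, and 8 higher and 3 lower adjusted over the list alone. This list was not called without TSC replicates 2 or 3 or CTC replicate 2 (adjusted p = 0.145, 0.0714 and 0.569), nor after thinning (adjusted p = 0.145).

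Glycolysis (median 0.33, or 0.51 without CTC replicate 2, 16 of 16 positive, camera adjusted p = 9.98e-05, and adjusted p = 0.373 with an estimated correlation) and epithelial identity genes (median 0.54, 25 of 28 positive, camera adjusted p = 1.25e-06, and adjusted p = 0.34 with an estimated correlation) lay higher with 0 single calls by edgeR over all genes, and 7 and 3 adjusted over the list alone. Unadjusted p under 0.05 was reached by 8 and 13 of their members, DESeq2 called 4 and 2, and limma-voom 4 each. The remaining 19 lists were not called, from adjusted p = 0.129 for cancer stem cell markers (median 0.57) to 0.941 for apoptosis regulators, NRF2 targets, self-seeding mediators and fibroblast markers. The stem cell list was called higher without CTC replicate 1 (adjusted p = 0.0299), with a stricter filter (adjusted p = 0.0468) and after thinning (adjusted p = 0.0195). Hypoxia response genes (median 0.27, adjusted p = 0.252) were called higher without TSC replicate 1 or CTC replicate 1 (adjusted p = 0.039 and 0.000327) and by limma-voom (adjusted p = 0.000739). The unfolded protein response list was called lower without CTC replicate 1 (adjusted p = 0.0322). DKK1 was lower in TSC (−1.23 ± 0.19, adjusted p = 0.00557) and TCF7 higher (1.40 ± 0.26, adjusted p = 0.0243). Median, mean and test differed in sign for cell cycle, NF-κB and inflammatory cytokines, apoptosis regulators, self-seeding mediators, angiogenesis factors, lysosome and autophagy, NRF2 targets and fibroblast markers.

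Of the 20 genes with the largest changes between TSC and CTC, the 10 lower in TSC passed in all 8 fits with 1 library left out, and 0 of the 10 higher in TSC did. The count of 128 became 696 and 36 without TSC replicates 1 and 3, 76 and 66 without PC replicates 1 and 2, and 48 without CTC replicate 2. Genes higher in TSC had a median GC content of 57.9%, against 46.6% for genes lower in TSC, and 36 of the 53 and 71 of the 75 were called again with GC content and length corrected for.

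Further genes, chosen beforehand for background knowledge of self-seeding and of the tissues involved, did not pass in any comparison or were not tested. In simulated data 12.1% of 2-fold changes were recovered for CTC against PC, so a gene that did not pass is not shown to be unchanged. CD44, a cell adhesion and stem cell marker gene, was at 1734 CPM in PC, 2438 in TSC and 1919 in CTC (adjusted p = 0.282 and 0.65 against PC), PROM1, the CD133 gene, at 39.5, 41.1 and 26.6 CPM (adjusted p = 0.944 and 0.175), the fascin gene FSCN1 at 397, 437 and 286 CPM (adjusted p = 0.828 and 0.155) and the E-cadherin gene CDH1 at 162, 140 and 96.5 CPM (adjusted p = 0.766 and 0.079). VEGFA, CA9, MKI67, CDX2, COL1A1, CXCL1 and CXCL8 were not called in any comparison. IL6, KRT20 and AFP were at 0 in all 8 libraries, and MMP1, VIL1, ALB, APOA1, PECAM1 and HSPA1A did not reach the count minimum of the test. Symbols of overlapping genes and of near-identical copies remain uncertain, since the sources used here do not state whether counting used strand or how shared reads were treated.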

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

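Tests of the blood-cell, interferon and CTC-lower patterns were chosen after the results were seen, whereas the regrouping of the TSC and PC libraries was fixed beforehand. The TSC against CTC contrast, which tests whether the TSC and CTC differences from PC are equal, called 128 genes and 11 lists. A rule chosen after results were seen picked 3 of these for a closer look. It took genes called in all 3 comparisons, and lists called in all 3 with opposite directions against PC. The interferon and immediate early lists, called in all 3 with the same direction against PC, were left out by it. FOSB fell less in TSC than in CTC (log2 difference 1.41, adjusted p = 0.0225), and the call was lost without TSC replicate 3 (adjusted p = 0.119), without CTC replicate 2 (adjusted p = 0.194) and with a fold minimum of 1.5 (adjusted p = 0.113). IFI6 fell more in TSC (difference −1.28, adjusted p = 0.0293), and the call was lost without the same 2 libraries (adjusted p = 0.148 and 0.176) and with the fold minimum (adjusted p = 0.179). The histone list differed by a median of 1.02, with 0.38 in TSC and −0.68 in CTC against PC, and adjusted p = 0.541 with an estimated correlation. Against PC the list was not called in TSC without TSC replicate 3 or PC replicate 3 (adjusted p = 0.783 and 0.202), nor in CTC without CTC replicate 2 (adjusted p = 0.139).

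Blood-cell genes were higher in CTC. Had a trend with GC content and length been the cause, correction would have taken the leukocyte median below 0.5 of its value, and it was 5.89. The largest deviation of a GC class was −0.43, in CTC replicate 1, so this test could hardly have come out otherwise. The values show only that the GC trend is small beside the uncorrected median of 6.22. Cells of the blood could be the source, but 21 of 45 erythroid and leukocyte markers were at 0 in both CTC libraries, and 16 of these were at 0 everywhere in a table that also lists housekeeping genes at 0, so the count decides nothing. Reads of the host counted on human genes could give the pattern too. Pseudogenes were not clearly enriched among the genes higher in CTC (odds ratio 1.51, 95% interval 0.543 to 3.39, Fisher's exact test, two-sided p = 0.304). With 6 pseudogene rows among these 200 genes the interval is wide, so the test does not decide on host reads. Blood cells of the host would themselves bring host reads, so these sources are not separate. They and a change in the tumour cells cannot be told apart, since all CTC libraries and no others came from blood.

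Interferon genes were lower in TSC. Depth, GC content with length, and a single library were examined as causes. The list stayed called, with a median of −1.27 after thinning and −1.27 after correction for GC content and length. The largest deviation of a GC class in a TSC or PC library was 0.274, small beside the uncorrected median of −1.16. Thinning keeps the expected ratios between libraries. Neither step could thus be expected to move the median far, and they decide little about these causes. The list also stayed called with each TSC or PC library left out, with a median of −1.07 at the nearest to 0. The regroupings of the 6 TSC and PC libraries number 10, and 1 of them, the real one, gave 72 genes, while the highest of the others gave 0 by edgeR (1469 genes at an unadjusted p under 0.05 in the real grouping, 90 to 1117 in the others). With 10 regroupings a share under 0.05 cannot be reached. A difference between self-seeded and other tumour cells remains a hypothesis, and handling that differed between these groups was not tested.

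Genes lower in CTC were rich in GC. Of 359, 237 were called again after correction for GC content and length and 150 after thinning. The largest deviation of a GC class was −0.43, against a median fold change of −1.52 for the 359, so the correction could hardly have ended all calls. The values show only that the GC trend is small beside that median. Thinning cannot restore transcripts missed in a shallow library, so it does not decide on depth. The 122 not called again after the correction went from a median of −1.28 (median SE 0.301) to −0.72 (median SE 0.244) and lost their call because the fold shrank. In these the median was −1.21 with CTC replicate 1 alone and −1.34 with replicate 2 alone, so the fall was not larger in replicate 1, which has the steeper trend. The median difference of 0.082 (SE 0.054) lies within 2 SE of 0. As the correction itself picked these genes, a GC trend and a change in the cells cannot be told apart for them, and a trend may account for that part.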

How the results depend on the processing

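The GC and length correction and the thinning were chosen after the data were seen, and the other alternatives before. Of the 174 calls of named genes, 173 were kept with DESeq2 size factors, 174 with no filter and 65 of 173 without CTC replicate 2. Of the 36 list calls, 5 were kept with an estimated correlation and 6 with fry. In the order TSC against PC, CTC against PC and TSC against CTC, the calls of 72, 559 and 128 genes became 355, 1535 and 728 with no filter, 191, 1125 and 390 with DESeq2, 553, 1660 and 440 with limma-voom, 128, 1409 and 82 with only the 2 groups, and 19, 141 and 47 with a fold minimum of 1.5. GC and length correction gave 175 for TSC against PC, and thinning 286 and 71 for the comparisons with CTC, where fewer counts limit what is called. The 9, 16 and 11 lists became 1, 2 and 2 with an estimated correlation and 1, 3 and 2 with fry. The overlap of 32 became 213, 88, 248, 61, 6, 19 and 75 with no filter, DESeq2, limma-voom, 2 groups, the fold minimum, thinning and GC correction. The tally of 115 genes that differ between the effects became 596, 303, 373, 44 and 58 with no filter, DESeq2, limma-voom, the fold minimum and thinning.

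With each library left out, the gene counts ran from 10 to 153, from 35 to 1575 and from 36 to 696, the list counts from 5 to 11, from 13 to 17 and from 8 to 14, the overlap from 2 to 85 and the tally from 35 to 574. Where a lone CTC library is left, it is assumed to vary like the other groups. The replicate block gave 67, 261 and 61 calls (the last 18 higher and 43 lower in TSC) and a tally of 56, and kept 118 of the 174 calls of named genes and 33 of the 36 list calls. FOSB was not called between TSC and CTC (adjusted p = 0.0574). Nor were oxidative phosphorylation and integrins in CTC against PC (adjusted p = 0.0652 and 0.0809) and extracellular matrix in TSC against CTC (adjusted p = 0.088). Extracellular matrix in TSC against PC and stem cell markers in CTC against PC were called lower (adjusted p = 0.0368 and 0.0356). Whether the numbers pair the samples is not known. TSC and PC libraries of the same number had correlations of deviations of 0.187, −0.336 and 0.129. Those of unlike number ran from −0.431 to 0.402, and so few libraries cannot decide the question. The median of nuclear noncoding RNAs went from −0.64 to −0.25 in CTC against PC (adjusted p = 0.963) and from 0.55 to 0.026 in TSC against CTC (adjusted p = 0.962) when small noncoding genes were removed, which takes out members of the list, and the direction of its test turned. FGFBP1 turned to −0.386 in CTC against PC without CTC replicate 2 and was at 4.56 without CTC replicate 1. The first value rests on CTC replicate 1, where FGFBP1 was at about the floor of 3 counts, so its sign is not resolved. Apart from settings whose construction leaves fewer genes or samples, the cause was not tested. The stricter filter and thinning left too few erythroid members for a value.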

Other observations

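Fisher's test along the chromosomes was fixed before its result was seen, and the test of chromosome medians was chosen afterwards. The 19 genes higher in both TSC and CTC than in PC could lie on a gained chromosome or mark a clone, and Fisher's exact test over chromosomes gave a smallest adjusted p of 1, with at most 2 of the 19 on any chromosome. The median log2 fold change of the numbered chromosomes and X in TSC against PC ran from −0.072 to 0.051 (SE 0.016 for the highest), where 1 copy gained on 2 in all cells would give 0.585. This argues against the gain of a whole chromosome in all TSC cells. In CTC against PC the medians ran from −0.293 (chromosome 19) to 0.193 (chromosome 13) and were not tested in this way. The bound set in advance, that 0 chromosomes pass, was met, so no chromosome was found to hold more of the 19 genes than its share. This does not exclude the gain of a small region that holds few of these genes. Such a gain, a gain in part of the cells or a clone difference stays open.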
